A study of Arabidopsis thaliana with 6 samples.

How the data were processed

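Gene-level values of RNA sequencing from 6 leaf samples were used, 1 per genotype (Col-0, lsm1a lsm1b) and stress (cold, PEG, NaCl), with groups taken from the sample labels. The deposited values were whole-number read counts per gene, 1 file per sample, and were used as deposited. Per the submitters' processing notes the TAIR10 genome, TopHat2 and DESeq2 were used, without versions, and the tool that counted the reads is not given in the sources used here. Nothing in the labels says whether a column pools plants, and no column holds separate replicates. Per the labels, the libraries followed standard Illumina protocols, and strand is not given in the sources used here.

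The files were checked first. They list 18168 genes for cold, 18734 for PEG and 19468 for NaCl, 20297 in any and 16962 in all 3. Every listed gene had at least 1 RPKM, computed from the deposited counts and gene lengths, in at least 1 of the 2 libraries of its stress, so a gene not listed was low in both and the sums are those of listed genes. In 270 rows for NaCl and 1 for PEG the transcript name contradicted the locus code, and the coordinates fitted the code in each of these rows, so the locus code was used. The cold files have no locus code, and the locus was taken from the transcript name there. Symbols and products came from the reference annotation (TAIR10.1), which held 20058 of the listed loci, and 239 were used by code. Coordinates are those of the files (TAIR10). No row was a total or named no gene. Total counts ranged from 10289392 to 22639128.

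Within a stress, counts were scaled by TMM (edgeR 4.0.16, R 4.3.3) and the log2 ratio of the 2 libraries was taken from edgeR's log2 CPM with a prior count of 2. The interval beside a ratio is the exact binomial (Clopper-Pearson) 95% interval of the 2 counts after scaling, and covers counting error only. A gene was counted as higher or lower when the ratio was at least 2-fold and the higher library had at least 5 CPM. Against a library with 0 counts, the fold given after 'at least' was computed with a floor of 3 counts per library. It is not the limit of the 95% counting interval, which lies nearer to no change. Across stresses, edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, filterByExpr on genotype, TMM, two-sided, Benjamini-Hochberg adjusted p under 0.05) was fitted to the 6 libraries with stress as a block. The stress pairs stand in for replicates, so the spread holds replicate error and any difference of the genotype effect between stresses. PEG was compared with NaCl in the same fit. Cold was not compared with the plate stresses, because growth medium and duration differed with it.

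Gene lists were fixed before the data were examined: decapping, cold response, ABA metabolism and response, osmotic, ion transport, photosynthesis, defence, jasmonate, ethylene, zinc finger and touch, heat shock, oxidative stress, flavonoid, clock and senescence genes, markers of root, flower, seed, shoot meristem and guard cell, and by annotation cytosolic ribosomal proteins, chloroplast, mitochondrial and rRNA genes. One cold-response gene, COR28, could not be matched by name to the annotation and was left out. In each stress the median of a list was placed among 10000 random lists of the same size, matched in 20 expression bins. Across stresses camera (limma 3.58.1, preset correlation 0.01) was run, with an estimated correlation and fry beside it. The text names LSM1A and LSM1B first, then per stress up to 10 of the largest and up to 10 of the smallest ratios of nuclear protein-coding genes past the rule of size whose interval excluded 1, up to 4 members per list and stress with the largest ratios past that rule, and up to 10 of the highest and up to 10 of the lowest genes past the threshold in each test, with the same sign in all 3 stresses for the genotype. Genes named beyond this rule were chosen after their values were seen.

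Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors, total count scaling, prior counts of 0.5 and 10, level limits of 1 and 20 CPM, fold limits of 1.5 and 4, other filters, no stress block, each stress pair left out, and organelle genes left out. One more, without the genes of chromosomes 1 and 5, was chosen after seeing the data. The functions were tested on simulated counts with the means and library sizes of the data, a biological coefficient of variation of 0.236 and 200 changed genes. The test across stresses recovered 35.8% of genes changed 2-fold, 98.5% of those changed 4-fold and 100% of those changed 16-fold, and called 4 of 16715 unchanged genes. The changed genes were not drawn from genes of low count. Every simulated gene had the same coefficient of variation and, where changed, the same fold in each stress. Recovery in the data, where these differ between genes and stresses, can be lower and is not known.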

Results

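RNA was sequenced from leaves of 2-week-old Arabidopsis thaliana plants of the Col-0 accession and of the lsm1a lsm1b double mutant. LSM1A and LSM1B are the alternative first subunits of the cytoplasmic LSM1-7 ring, which binds the end of deadenylated mRNAs and promotes removal of their cap before decay. Each genotype was sampled in 3 stresses. In the cold treatment, soil-grown plants were kept at 4 °C for 24 h. In the drought treatment, plate-grown plants were moved to medium with 55% polyethylene glycol (PEG) for 10 h, and in the salt treatment to medium with 150 mM NaCl for 10 h. There was 1 library per genotype and stress, 6 in all, and unstressed plants were not analysed here. Differences between genotypes within a stress therefore have no replicate check and no p-value, and the intervals given for them cover counting error only. Total gene counts were 12422329 (Col-0) and 10289392 (lsm1a lsm1b) in cold, 20527483 and 18043773 in PEG, and 20183174 and 22639128 in NaCl. A value given as a log2 ratio is lsm1a lsm1b over Col-0, positive where the mutant library was higher.

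The mutated genes were measured first. LSM1A (AT1G19120, TAIR10 chromosome 1, 6608115 to 6609369) had 206, 246 and 273 counts in the Col-0 libraries of cold, PEG and NaCl, and 10, 26 and 12 in the mutant libraries. The Col-0 level was 15.5-fold higher in cold, 8.37-fold in PEG and 21.8-fold in NaCl. LSM1B (AT3G14080, chromosome 3, 4667365 to 4669194) had 152 and 39 counts in cold (log2 ratio -1.73, 95% counting interval -2.33 to -1.27) and 207 and 98 in PEG (-0.98, -1.35 to -0.64). In NaCl it had 195 counts in Col-0 and 439 in the library labelled lsm1a lsm1b (1.0, 0.76 to 1.26), the direction opposite to its label. All 16 genes at least 8-fold lower in both cold and PEG and measured in NaCl were at least 2-fold lower in that library, and directions in NaCl are given for the library as labelled. Of the other LSM1-7 subunits and decapping factors, LSM3A (log2 ratio 1.11 in PEG and 1.18 in NaCl) and the 3'-to-5' exonuclease SOV (1.24 and 2.03) were at least 2-fold higher in both plate stresses. The remaining members of this list of 22 genes, with DCP1, DCP2, VCS, PAT1 and XRN4 among them, differed by less than 2-fold in every stress.

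**Figure D1:**
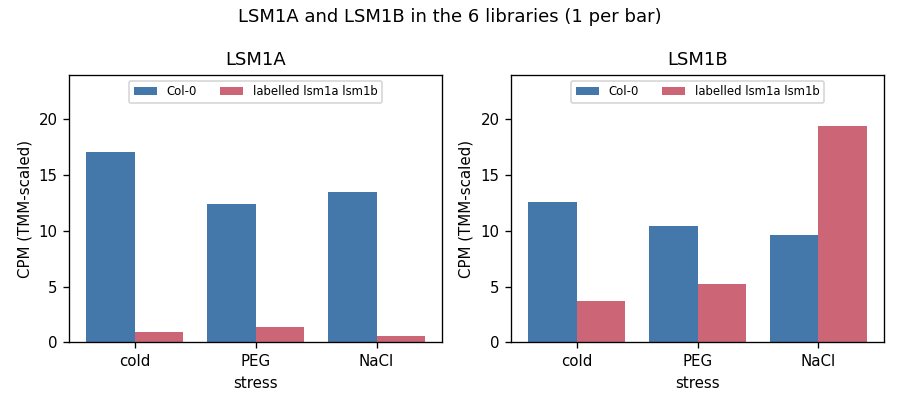
CPM (TMM-scaled) of LSM1A and LSM1B in the 6 libraries, 1 library per bar, by stress. LSM1A was between 8.37-fold and 21.8-fold lower in the mutant libraries, whereas LSM1B was lower in cold and PEG and higher in NaCl.

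The cold comparison asks which transcripts differed between the Col-0 and lsm1a lsm1b libraries of chilled leaves. Salicylic acid and defence genes were higher in lsm1a lsm1b almost throughout the list: 21 of the 22 measured members were at least 2-fold higher and 0 were lower, with a median log2 ratio of 3.61. The transcription factor gene WRKY46 went from 8 to 285 counts (5.01, 4.34 to 6.56), the pathogenesis-related gene PR1 from 39 to 950 (4.71, 4.33 to 5.29), and PBS3, which acts in salicylic acid synthesis, from 45 to 1053 (4.67, 4.30 to 5.19). FMO1, a monooxygenase of systemic immunity, had 0 counts in Col-0 and 54 in the mutant, at least 20.4-fold higher. All 11 measured genes of the list of stress zinc fingers and touch genes were at least 2-fold higher (median 2.86), among them ZAT7 (2 and 134 counts, 5.22, 4.37 to 9.31), ZAT10 (3.97), AZF1 (3.88) and the calmodulin-like TCH3 (2.97). Both medians lay above those of all 10000 random lists matched on expression.

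Several hormone-related lists were on the higher side in cold. Of the ethylene and ERF genes, 9 of 17 were at least 2-fold higher and 0 lower (median 1.0), led by ERF11 (3.69), ERF5 (2.99), ERF6 (2.95) and ERF105 (2.85). Of the jasmonate genes, 6 of 16 were higher and 0 lower (median 0.41, percentile 99.9), led by JAZ1 (2.62), LOX4 (2.61), JAZ5 (2.21) and MYC2 (2.03). Abscisic acid (ABA) response genes had 6 higher and 1 lower of 24 (median 0.25, percentile 99.6): the phosphatase genes HAI1 (2.24), AHG3 (1.69) and HAI2 (1.57) and the transcription factor gene NAC019 (1.99) were the 4 farthest from 0. Of ABA metabolism genes, NCED5 (8 and 127 counts, 3.85) and NCED3 (2.16), both encoding the cleavage step of ABA synthesis, and CYP707A2 (1.18) were higher and BGLU18 (-1.25) was lower, and the list median (0.24, percentile 93.9) lay within its random range. Of 13 oxidative stress genes 4 were higher, OXI1 (3 and 77 counts, 4.12, 3.26 to 7.17), RBOHF (1.96), RBOHD (1.08) and GSTF8 (1.06).

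Genes of cold acclimation and light harvesting were on the lower side in the cold-treated mutant. Of 18 cold-responsive genes, 4 were at least 2-fold lower and 0 higher (median -0.70, below all random lists): ADH1 (-2.08), COR27 (-1.42), RAV1 (-1.28) and COR413IM1 (-1.05). Of 29 photosynthesis genes, 7 were lower and 0 higher (median -0.51, below all random lists), with LHCB1.1 (-2.19), LHCB1.3 (-1.53), LHCB1.2 (-1.23) and LHCB5 (-1.19) farthest from 0. The LHCB1 genes are near-identical copies, and reads could be split between them. Of 16 osmotic and dehydration genes (median -0.40, percentile 0.52), P5CS1, the rate-limiting enzyme gene of proline synthesis (-1.70), and GOLS1 (-1.46) were lower, and GOLS2 (2.22), DREB2A (1.26) and RS5 were higher. Senescence genes went both ways, with WRKY6 (2.57), SAG21 (2.33) and SAG101 higher and SEN1 (-2.52) and NAP (-1.51) lower, so that their median (-0.35) and mean (0.06) had opposite signs. CHX17 (2.99), MBF1C (1.86) and the clock gene PRR9 (1.49) were higher, and ELF4 (-1.41) and the guard-cell channel gene KAT1 (-2.34) lower. The clock list of 13 genes, also fixed as a check on sampling time, had a median of -0.32 (percentile 1.59), below its random range. Its mean (-0.26) lay at percentile 7.36. Whether the 2 libraries were sampled at different times of day was not tested. All 16 flavonoid genes measured differed by less than 2-fold in cold, with a median of -0.28 (percentile 1.99) just below the random range.

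By size, the genes most elevated in the cold-treated mutant were AT5G24240, a phosphatidylinositol 4-kinase gamma-like gene (2 and 748 counts, log2 ratio 7.69, 6.87 to 11.78), and AT3G13610, an oxoglutarate-dependent oxygenase gene, with 0 and 315 counts (at least 119-fold). They were followed by ARI12 (0 and 222, at least 83.9-fold), AT5G26270 (6.50), AT5G52730 (0 and 117, at least 44.2-fold), ARD3 (5.81), AT5G44570 (3 and 242 counts, 5.75, 4.95 to 8.80), AT5G36900 (0 and 99, at least 37.4-fold), AT1G23850 (2 and 190, 5.72, 4.88 to 9.81) and AT4G10500 (2 and 163, 5.50, 4.65 to 9.59). The most reduced were AT5G49440 (1504 and 4 counts, -7.82), the TRAF-like gene ZW9 (3488 and 14, -7.60), the thionin gene AT1G66100 (-7.35), the TIR-NBS-LRR resistance gene AT1G63880 (-6.98) and ECS1 (9695 and 69, -6.92). AT1G23950 (248 and 0, at least 72.9-fold lower), AT5G49640 (469 and 2, -6.74, -10.74 to -5.83), AT1G65190 (-6.56), AT5G28919 (-6.49) and AT5G15360 (286 and 1, -6.47, -13.29 to -5.49) followed. All 10 of these reduced genes lie on chromosomes 1 and 5, but not all were reduced in the other stresses: AT5G15360 was higher in PEG (7 and 181 counts, 4.42) and NaCl (15 and 282, 3.91), and ZW9 (-1.05 and -0.80) and AT5G28919 (-1.33 and -0.76) were less reduced there. Of 14816 genes with at least 5 CPM in the higher library, 1224 (8.26%) were at least 2-fold higher and 760 (5.13%) at least 2-fold lower. In simulated libraries with the spread of the 6-library fit, 5.26% of unchanged genes passed the same rule in either direction in cold, against 13.4% of genes in the data.

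In PEG, which imposes osmotic drought, the clearest difference was in anthocyanin synthesis. Of 19 flavonoid and anthocyanin genes, 12 were at least 2-fold lower in lsm1a lsm1b and 0 higher (median -1.15, below all random lists). The regulator gene TT8 had 227 and 6 counts (-4.76, -6.62 to -4.01), and the late pathway enzyme genes LDOX (1465 and 79, -4.09, -4.47 to -3.80) and DFR (2081 and 117, -4.04, -4.35 to -3.80) and the vacuolar transport gene TT19 (-3.35) followed. Of 16 heat shock genes, 5 were lower and 0 higher (median -0.72, below all random lists): the chloroplast chaperone gene HSP21 (302 and 5, -5.37, -7.46 to -4.59), HSP17.6A (-1.72), HSP70B (-1.68) and HSP22 (-1.66) were the farthest from 0. Seed storage genes, used as markers of another organ, differed by at least 2-fold in all 9 members but in both directions: SESA4 (-4.13), CRU2 (-3.69) and SESA3 (-2.69) were lower, and the oleosin gene OLEO2 (2.21) was higher.

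Ion transport genes were higher in PEG in 3 of 15 members and lower in 0 (median 0.30, percentile 99.8), namely the guard-cell potassium channel gene GORK (1.70) and the vacuolar exchanger genes CAX3 (1.56) and CAX1 (1.03). PR5 (22 and 408 counts, 4.18, 3.68 to 4.99) and WRKY46 (22 and 181, 3.01, 2.48 to 3.84) were the 2 of 10 measured defence genes that were at least 2-fold higher (list median 0.70, percentile 99.9). Of photosynthesis genes, LHCB2.1 (1.83), LHCB2.2 (1.60) and RBCS3B (1.09) were higher and LHCB4.1 (-1.18) lower, with 25 within 2-fold. Of 82 chloroplast-encoded genes 22 were at least 2-fold lower and 0 higher (median -0.74), and these genes made 3.18% of the counts in Col-0 and 2.05% in the mutant. In the ABA lists, NCED9 (-2.67), BGLU18 (-2.51), AFP3 (-1.13) and HAB1 (-1.05) were lower and NAC019 (1.11) higher. JAZ9 (-2.37), VSP2 (-1.69) and VSP1 (-1.33) were lower and LOX2 (1.03) higher among jasmonate genes. ERF105 (1.64), ERF11 (1.15), ABR1 and TCH3 (1.47) were higher, and ACS7 (-1.19) and ZAT10 (-1.0) lower. COR15A (-1.18), COR413IM1 (-1.13), the raffinose gene RS2 (-1.27), GSTU25 (-1.99), APX2 (-1.40) and CCA1 (-1.51) were lower, and COR27, PRR7 and CDF1 (1.07, 1.07 and 1.01) and the root iron transporter gene IRT1 (1.87) higher. All 12 measured senescence genes differed by less than 2-fold, with a median of 0.50.

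The genes most elevated in PEG were the late embryogenesis gene M17 (16 and 2754 counts, 7.34, 6.81 to 8.32), the EIN3-family gene AT5G10120 (1 and 320, 6.80, 5.92 to 13.72), AT4G04402 (0 and 149, at least 52.7-fold), AT5G27010 (1 and 192, 6.07, 5.18 to 12.98) and AT2G05915 (6.06). The extensin gene AT2G27380 (5.92), AT1G63540 (0 and 114, at least 40.3-fold), AT5G36900 (1 and 166, 5.86, 4.96 to 12.77), AT5G25920 (0 and 96, at least 34.0-fold) and AT5G55410 (5.33) came next. The most reduced were AT5G66052 (7955 and 7, -9.71) and AT5G66053 (2173 and 1, -9.44, -16.30 to -8.52), which overlap on opposite strands (chromosome 5, 26416661 to 26416807 being the span of AT5G66053), so their reads may not have been told apart. AT1G23960 (1128 and 3, -7.75, -10.75 to -6.92), AT5G49640 (423 and 0, at least 133-fold), the kinase gene AT1G72760 (160 and 0, at least 50.3-fold), AT5G50565 (151 and 0, at least 47.4-fold), AT5G49440 (-6.03), the resistance gene AT5G51630 (178 and 2, -5.43, -9.45 to -4.52), HSP21 and AT5G45490 (-5.22) followed. Of 15070 genes past the level limit, 542 were at least 2-fold higher and 550 lower. With total count scaling these became 690 and 438, so the share of higher genes among those past the rule went from 49.6% to 61.2%. In simulated libraries 4.66% of unchanged genes passed the rule in either direction in PEG, against 7.25% of genes in the data. As in cold, the simulation had 1 spread for all genes, so the gap does not measure an excess over noise.

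In NaCl, seed storage and oil body genes were far higher in the library labelled lsm1a lsm1b. The seed list was fixed as markers of another organ, so seed material in 1 library cannot be told from a genotype difference. All 6 measured members of the seed list were at least 2-fold higher (median 4.14, above all random lists), with CRU3 (74 and 4987 counts, 5.87, 5.58 to 6.26), SESA2 (4 and 378, 5.85, 5.03 to 8.28), OLEO1 (4.23) and SESA1 (4.06) the farthest from 0. Anthocyanin genes were lower, as in PEG: 9 of 19 flavonoid and anthocyanin genes were at least 2-fold lower and 1, MYB12, was higher (median -0.43, percentile 0.06). UF3GT (350 and 35, -3.41, -4.03 to -2.98), DFR (-3.34), LDOX (-3.06) and TT8 (-2.58) were the farthest from 0. Stress zinc finger and touch genes were 5 lower and 0 higher of 10 (median -1.0, below all random lists), with SZF1 (6941 and 849, -3.19, -3.30 to -3.09), TCH2 (-1.80), ZAT10 (-1.29) and TCH4 (-1.24), the opposite side from cold.

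Ethylene and ERF genes were also on the lower side in NaCl, 6 lower and 1 higher of 22 (median -0.38, percentile 0.18): ERF104 (-2.71), ACS6 (-1.91), ERF105 (-1.84) and ERF4 (-1.64) were the farthest from 0. Of the defence genes, PR5 was higher (47 and 1873 counts, 5.10, 4.73 to 5.60), whereas WRKY70 (-3.14), WRKY40 (-1.82), CBP60G (-1.46) and SARD1 (-1.08) were lower, and the list median of -0.32 (percentile 3.05) lay within its random range. JAZ9 (-2.16), LOX4 (-1.38) and MYC2 (-1.31) were lower and VSP1 (1.73) higher in the jasmonate list (median -0.56, percentile 0.01). ABA response genes had 6 higher and 0 lower of 27 (median 0.36, above all random lists), led by HB12 (1.46), RD20 (1.25), ABI5 (1.09) and HB7 (1.03). In the cold-responsive list the 3 CBF transcription factor genes were lower, CBF1 (1046 and 118 counts, -3.29), CBF2 (-2.51) and CBF3 (-1.22), as was RAV1 (-1.57), while the dehydrin genes LTI30 (1.64), COR47 (1.41) and ERD10 (1.24) were among the 5 that were higher (list median 0.37, mean 0.01). NCED5 (8 and 142, 3.70, 2.97 to 5.22), GORK (1.70), CAX3 (1.67) and CHX17 (1.23) were higher, and BGLU18 (-3.08), CYP707A3 (-2.71) and RS2 (-1.23) lower. CSD2 (1.49), GSTU24 (1.34), NAC092 (1.31), PRR7 (1.36), MYB60 (1.47) and KAT1 (1.0) were higher, and ROF2 (-1.70), HSP23.5 (-1.55) and SAG20 (-1.04) lower. Of photosynthesis genes, LHCB2.1 (1.43) and LHCB2.2 (1.14) were higher and LHCB1.3 (-1.05) and PETE1 (-1.04) lower.

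The largest ratios in NaCl were those of AOP3, a glucosinolate dioxygenase gene (1 and 1177 counts, 8.51, 7.56 to 15.34), AT2G05915 (7.28), SESA5 (0 and 180, at least 53.5-fold), AT1G63540 (0 and 179, at least 53.2-fold), the cupin gene PAP85 (1 and 266, 6.37, 5.40 to 13.20), AT4G35720 (5.96), AT5G41660 (0 and 126, at least 37.5-fold), CRU3, SESA2 and OLEO4 (0 and 116, at least 34.5-fold). Among the smallest were those of AT5G66052 (-7.77), AT5G49440 (-7.62), AT5G66053 (657 and 2, -7.49, -11.57 to -6.67), AT5G51630 (319 and 0, at least 119-fold lower), ECS1 (-6.82), AT5G45490 (-6.70), AT5G49640 (263 and 1, -6.58, -13.51 to -5.71), AT1G23960 (-6.45) and AT1G72840 (170 and 1, -5.95, -12.89 to -5.08). Of 15906 genes past the level limit, 875 (5.50%) were at least 2-fold higher and 709 (4.46%) lower. In simulated libraries 4.85% of unchanged genes passed the rule in either direction in NaCl, against 9.96% of genes in the data. The same limit of the simulation holds here.

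**Figure D2:**
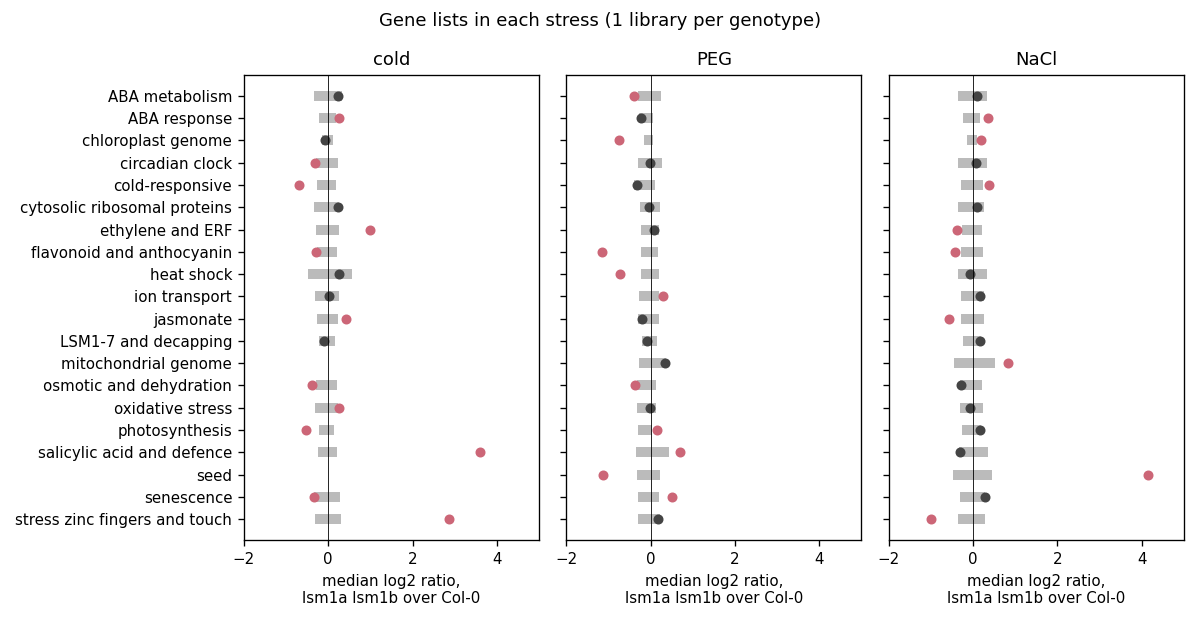
Median log2 ratio (lsm1a lsm1b over Col-0) of each gene list in cold, PEG and NaCl (points, red where outside the grey bar), 1 library per genotype and stress, with grey bars giving the central 95% of medians of 10000 random lists matched on expression. The defence list stood at 3.61 in cold, and the list of zinc finger and touch genes at 2.86 in cold and -1.0 in NaCl.

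Taking the 3 stress pairs as replicates asks which genes differed between the genotypes whatever the stress. Among the genes called were 4 aquaporin genes, named after their values were seen, with no aquaporin list fixed or tested: the tonoplast aquaporin genes TIP2;2 (log2 fold change 3.14 ± 0.22 SE, adjusted p = 0.0302, edgeR quasi-likelihood test) and GAMMA-TIP (2.40 ± 0.19, adjusted p = 0.0351) and the plasma membrane aquaporin genes PIP2B (3.10 ± 0.28) and RD28 (2.96 ± 0.27), both with an adjusted p of 0.0465, were higher in lsm1a lsm1b in 3 of 3 stresses. PIP2B and RD28 are neighbouring close copies on chromosome 2 and reads could be split between them. None of the 4 passed without the PEG pair or without the NaCl pair. With the genes of chromosomes 1 and 5 left out, chosen after seeing the data, 1 higher gene passed, which was not an aquaporin gene. Other aquaporin genes did not pass, such as PIP1A (2.25), PIP3 (0.06) and PIP2E (-0.58). The ABA synthesis gene NCED5 (TAIR10 chromosome 1, 10571340 to 10573365) was higher by 4.16 ± 0.30 (adjusted p = 0.0315). LSM1A fell by 3.94 on the log2 scale (SE 0.36, adjusted p = 0.0465), and LSM1B, with -0.54 ± 0.57, did not pass (adjusted p = 0.692).

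Among the 19 genes past the threshold on the higher side, the 10 with the largest fold change were AT5G36900 (7.19), AT4G35720 (5.30), AT5G59760 (4.91), AT1G20070 (4.42), NCED5, the ERF-type gene AT4G28140 (3.78, SE 0.19), the receptor-like kinase gene ARCK1 (3.64), the kinase gene AT5G24080 (3.56), ERF53 (3.55) and AT4G18630 (3.37). On the lower side 17 genes passed, and those farthest from 0 included AT5G66053 (-8.89), AT5G66052 (-8.68), AT5G49640 (-8.36), AT1G23960 (-7.50), AT5G49440 (-7.34), AT5G51630 (-7.31), AT5G50565 (-6.90), the TIR-NBS-LRR gene AT1G72840 (-6.49) and AT5G50665 (-6.32). All 36 genes had the same sign in the 3 stresses. The auxin repressor gene SHY2 (-1.52 ± 0.14) was the lower gene closest to 0. All 17 lower genes lie on chromosomes 1 and 5, whereas 7 of the 19 higher genes do.

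The call of 19 higher and 17 lower genes, from 16927 tested with edgeR's quasi-likelihood test and the Benjamini-Hochberg adjustment, rests on 2 residual degrees of freedom. The same design gave 410 and 429 genes with DESeq2 and 43 and 28 with limma-voom. Without the cold pair 403 and 423 genes passed, and without the PEG or the NaCl pair 0 did, with 1547 and 1430 genes at an unadjusted p under 0.05 there and 2651 in the full set.

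**Figure D3:**
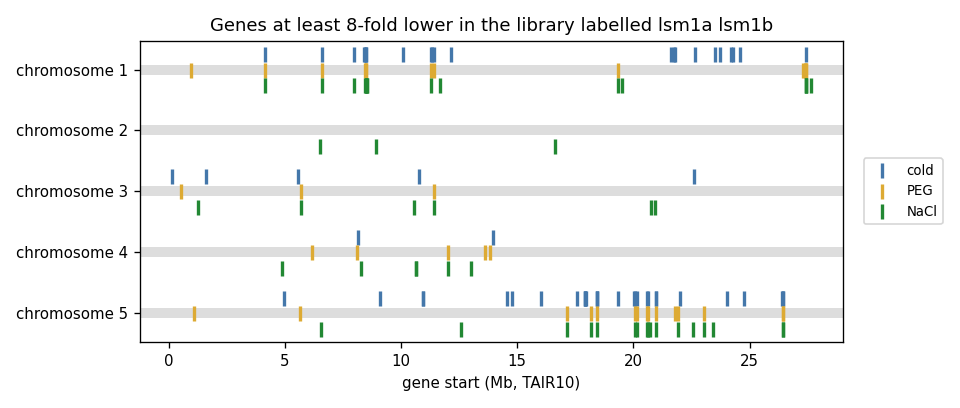
Start positions (TAIR10) on the 5 chromosomes of genes at least 8-fold lower in the library labelled lsm1a lsm1b than in Col-0 in cold, PEG and NaCl, 1 library per genotype and stress. Of the 103 genes at least 8-fold lower in any stress, 76 lie on chromosomes 1 and 5.

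Gene lists tested across the stresses with camera at a preset correlation of 0.01 gave 3 of 19 lists past the threshold. Flavonoid and anthocyanin genes were lower (median log2 fold change -0.75, camera adjusted p = 0.000275), as were chloroplast-encoded genes (-0.20, camera adjusted p = 0.00361). Salicylic acid and defence genes were higher (1.0, camera adjusted p = 0.00833), although their median within NaCl was below 0. The chloroplast-encoded median was -0.74 in PEG, but -0.09 in cold, within its random range, and 0.19 in NaCl, above it. With an estimated correlation each of the 3 lists had an adjusted p = 0.796, and fry gave adjusted p values of 0.746, 0.798 and 0.798, so none passed by either. No single gene of the 3 lists passed the adjustment over all genes. With p-values adjusted over the list alone, PR5 (4.11 ± 0.45) in the defence list, NCED5, CYP707A2 (0.99) and BGLU18 (-2.28) in ABA metabolism, LSM1A, LSM3A (1.01) and SOV (1.42) in decapping, CAX3 (1.39) in ion transport, RS5 (0.90) in the osmotic list and HSP18.2 (-2.84) in the heat shock list passed, whereas NCED5 and LSM1A alone did over all genes. HSP18.2 was of low level, with a mean of 2.84 CPM in Col-0 and 0.41 CPM in lsm1a lsm1b, below the limit of 5 CPM used within a stress.

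The genotype differences were compared between stresses over 13221 genes past the level limit in every stress, with no library shared between them. The log2 ratios of PEG and NaCl correlated across genes with Pearson's r = 0.659 (Spearman's rho 0.495), those of cold and PEG with 0.377 (0.240) and those of cold and NaCl with 0.358 (0.275). Genes are not independent replicates. PEG and NaCl shared 180 higher and 162 lower genes, where 10.8 and 12.9 would be shared by independent lists of these sizes. Cold shared 141 higher and 130 lower genes with PEG (19.6 and 16.8 by chance) and 159 and 153 with NaCl (25.2 and 22.5). In all 3 stresses 93 genes were at least 2-fold higher and 86 at least 2-fold lower. Opposite differences were found for 64 genes higher in cold and lower in NaCl (28.2 by chance) and for 16 the other way (20.1). SZF1, ZAT10, TCH2, ERF104 and ACS6 were among the 64. For cold and PEG these numbers were 20 and 6 (21.1 and 15.6 by chance), and for PEG and NaCl 8 and 4 (12.0 and 11.6).

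The comparison of PEG with NaCl shows how the 2 plate treatments, of the same length, differed whatever the genotype. Photosynthesis transcripts were lower in PEG: 16 of 29 list genes passed the threshold with lower levels in PEG and 0 with higher, among them LHCB3 (log2 difference -3.72, adjusted p = 0.0281, edgeR quasi-likelihood test), LHCB6 (-2.44), PSAD2 (-2.24), PETE1 (-2.20) and the small Rubisco subunit genes RBCS1A (-2.18) and RBCS2B (-2.19). ABA response genes were higher in PEG in 6 of 26 and lower in 0: RAB18 (2.54, adjusted p = 0.0294), RD29B (2.50), HB12 (2.15), LEA4-5 (2.03), ABF4 (1.46) and ABF2 (0.96). Adjusted over the list alone, 27 photosynthesis genes were lower and 15 ABA response genes higher in PEG. HSP70B (2.33), HSP70-4 (1.77) and HSP90.1 (1.28), the raffinose gene RS2 (2.23), P5CS2 (1.56) and ERD1 (1.79), and the chlorophyll breakdown genes PAO (2.16) and NYE1 (1.69) were higher in PEG. ERF2 (-2.83), ACO4 (-2.02), LOX3 (-2.40), OPR3 (-2.27), JAZ6 (-2.36), RAV1 (-2.72), CBL10 (-2.21) and RBOHD (-1.63) were lower.

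The 10 genes highest in PEG relative to NaCl were AT4G11910 (3.87 ± 0.39), the storage protein gene VSP2 (3.67 ± 0.71), AT5G39520 (3.61), AT5G54585 (3.54), ENODL1 (3.17), CYP89A9 (3.13), the chaperone gene ATERDJ3A (3.02), AT3G48020 (3.02), AT1G05340 (3.0) and SUE4 (2.99). The 10 on the NaCl side were IPMI1, of glucosinolate synthesis (-5.05 ± 0.29), the lipase gene AT1G29660 (-4.97 ± 0.49), AT5G19110 (-4.68), AT4G34950 (-4.57), the germin gene GER1 (-4.55), the expansin gene EXPB3 (-4.39), AT1G49750 (-4.39), the cell wall gene XTH31 (-4.38), AT5G39580 (-4.34) and AT4G28780 (-4.23). In all, 544 genes were higher in PEG and 902 higher in NaCl of 16927 tested. The same differences taken within Col-0 and within lsm1a lsm1b correlated across genes with r = 0.780. DESeq2 gave 1259 and 1781 genes, and the fit on the 4 plate libraries alone 2034 and 2827.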

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

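All tests in this part were chosen after the result was seen. Of the 103 genes at least 8-fold lower in lsm1a lsm1b in any stress, 76 (73.8%) lie on chromosomes 1 and 5, against 49.9% of all genes measured; because this pair was picked from the data, the excess was compared with 100000 random draws in which the fullest pair was chosen anew, and 1 draw was as high for the genes and 644 for 79 loci with neighbours within 50 kb joined (excess 3.28 SD, highest draw 4.87 SD). The joined loci thus lay above the central range of the draws. They were not above every draw, the bound set for excluding an explanation (a fixed pair, scored first, gave 68 draws as high). For the genes 8-fold lower, reads shared between neighbouring copies and an effect of LSM1-7 independent of gene position therefore both stay open. Of 4 sets computed, joined loci 2-fold lower in all 3 stresses exceeded every draw (4.84 SD, highest draw 4.46 SD). With joined loci taken as independent, this argues against both explanations for these loci as a set. Genes 8-fold higher in any stress or 2-fold higher in all 3 did not exceed the central range. Inherited chromosome segments that differ between the lines stay open too: of 51 genes of the 76 measured in every stress, 62.7% were at least 2-fold lower in all 3 (26.7% of 15 on the other chromosomes), while 3, with AT5G15360 and WSD1 among them, were at least 2-fold higher in another stress. For the call across stresses only 10 splits of the 6 libraries exist, and only some of them keep 1 library of each stress on either side, as the block requires. These are too few to exclude chance (1 split, the real one, gave 36 genes, and the highest other 0).

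The medians of the list of zinc finger and touch genes lay on opposite sides in cold and NaCl and differed by 3.86, those of ethylene and ERF genes by 1.38, and these differences between stresses were not tested. Over 4 scalings the lists differed by 3.86 to 3.95 and by 1.38 to 1.59, and the medians stayed on opposite sides with each. The ends of the random ranges of matched lists lay 0.66 and 0.51 apart. The lists were picked for lying outside those ranges on opposite sides, so larger differences were given in advance. The comparison with the random ranges therefore cannot decide whether library scaling contributed. Another 3 forms of the test had been dropped earlier because their outcome was hardly open. Growth on soil against plates cannot be told from an effect of the stress itself, because only the cold plants were grown on soil. Duration differed with it too, and the chilled plants had 40 µmol light against 90 µmol in growth. The median in PEG, the other plate treatment, was 0.18 and within its random range, so a median below the range was not shared by both plate treatments.

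LSM1B was lower in the mutant in cold and PEG and higher in the NaCl library labelled lsm1a lsm1b, with log2 differences of -2.73 (cold minus NaCl) and -1.98 (PEG minus NaCl), both untested. Swapped labels of the NaCl pair did not account for this: 100% of the 16 genes at least 8-fold lower in both cold and PEG were at least 2-fold lower in that library. Col-0 plants mixed into the library did not account for it either: LSM1A stood at 4.58% of its Col-0 level (2.0% to 6.96%) and LSM1B at 200% (169% to 239%). No biological explanation was tested.

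Other lists had medians outside their random ranges on opposite sides in 2 stresses, each an untested difference. The defence list (3.61 in cold, -0.32 in NaCl) is not among them, because its NaCl median lay within the random range. Chloroplast-encoded genes differed by -0.94 (PEG minus NaCl), and jasmonate genes by 0.98 (cold minus NaCl). Cold-responsive genes differed by -1.07 (cold minus NaCl), but in NaCl 5 were at least 2-fold higher and 4 lower, with a mean of 0.01. Photosynthesis genes differed by -0.67 and senescence genes by -0.85 (cold minus PEG), the senescence mean in cold being 0.06. Seed genes differed by -5.27 (PEG minus NaCl), but over different members: on the 6 genes measured in both stresses the medians were 1.15 and 4.14, on the same side.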

How the results depend on the processing

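Of 1787 values of 333 single genes under the alternatives, 1626 stayed, 95 moved, 66 were weaker and 0 reversed. A tested gene stayed if it kept its direction and side of the threshold, whatever its size. A ratio within a stress stayed if it kept its direction and lay within its main counting interval. Of 108 values of main results, 65 stayed and 43 moved. The counts of genes past the 2-fold rule followed the limits by construction. Higher genes in cold were 629 at a level limit of 20 CPM, 2118 at 1.5-fold and 507 at 4-fold, and lower genes 401, 1823 and 180. Higher genes in PEG were 926 at 1 CPM, 257 at 20 CPM, 1424 at 1.5-fold and 136 at 4-fold, and lower genes 295 at 20 CPM, 1493 at 1.5-fold and 87 at 4-fold. Higher genes in NaCl were 1335 at 1 CPM, 441 at 20 CPM, 1996 at 1.5-fold and 205 at 4-fold, and lower genes 446 at 20 CPM, 2014 at 1.5-fold and 152 at 4-fold. Genes higher and lower across the stresses were 410 and 429 with the DESeq2 Wald test, 43 and 28 with limma-voom and 1 and 4 with no stress block. Leave-one-out counts ranged from 0 to 403 (higher) and from 0 to 423 (lower). Without chromosomes 1 and 5, chosen after seeing the data, they were 1 and 0, with fewer genes tested. Genes higher in PEG and in NaCl were 1259 and 1781 with the DESeq2 Wald test and 2034 and 2827 with the PEG and NaCl libraries only. Correlations of the genotype effect at 20 CPM or more in all 6 libraries were 0.250 (cold and PEG), 0.236 (cold and NaCl) and 0.539 (PEG and NaCl). Lists past the threshold across the stresses were 0 with an estimated correlation and 0 with fry. Apart from the limits, the cause was not tested. The cold libraries had the fewest counts, which limits genes of low level there. Leaving out single replicates within a stress was not run, because no file holds replicate columns.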

Other observations

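The acetolactate synthase gene CSR1, named here after its values were seen, had 6094 counts in Col-0 and 31431 in lsm1a lsm1b in cold (log2 ratio 2.55), 8473 and 102200 in PEG (3.68) and 10020 and 93192 in NaCl (3.05). Across the stresses its adjusted p was 0.0546 (edgeR quasi-likelihood test).

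Some root marker transcripts were present in the leaf libraries of the plate treatments. Of the 11 root markers, 8 were listed in PEG and 8 in NaCl. At least 5 CPM in the higher library was reached by 3 of the 11 in PEG, 4 in NaCl and 1 in cold. The root beta-glucosidase gene PYK10 had 1206 (Col-0) and 1406 (lsm1a lsm1b) counts in cold, 29671 and 26036 in PEG and 37399 and 32230 in NaCl. The root auxin carrier gene PIN2 had 392 and 264 counts in PEG and 169 and 331 in NaCl, and was below the listing limit in cold. The samples are labelled leaves.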
